A study of Bos taurus with 8 samples.

How the data were processed

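RNA was sequenced from pools of 8 eight-cell Holstein cattle embryos. The 3 groups were embryos from in vitro fertilisation (IVF, 3 libraries), cloned embryos from somatic cell nuclear transfer (SCNT, 3 libraries) and cloned embryos that overexpressed the histone demethylase KDM4E (written KDM4E-SCNT, 2 libraries). Groups were taken from the labels. The labels do not say how KDM4E was overexpressed, which donor cells were used, how many hours after fertilisation or activation the embryos were collected, or whether the pools of a group came from separate batches. The p-values therefore measure only the spread between these samples, which may be technical.

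Per the labels' protocols, cDNA was made with SuperScript III, tailed with poly(A), amplified with Ex Taq, fragmented by Covaris and made into libraries with a NEBNext Ultra kit for an Illumina instrument. The submitters' processing notes name bcl2fastq 2.16, HISAT 0.1.6, StringTie 1.0.4, Bowtie2 2.2.5, RSEM 1.2.12 and the cattle build UMD3.1, without saying which step each did. The deposited files, 1 per library, hold FPKM, a fragment count divided by transcript length and library size, for 21258 features, to 2 decimals, per the file headers. Of these features, 16205 have Ensembl identifiers, 5052 are unannotated loci from the authors' transcript assembly and 1 is a RefSeq mRNA. A symbol was in the files for 14158 features. A further 314 were named through RefSeq accessions in a gene table of assembly ARS-UCD2.0, used for names only, and 13 mitochondrial genes were named from their descriptions. Where a symbol occurred more than once, 59 further features carry the symbol with their identifier. Coordinates are those of the files.

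A test on read counts had been planned. The files hold FPKM only, so the fallback written with that plan was used. Values were tested as log2(FPKM + 1), and every fold change is on that scale, which understates the change of low genes. Features with FPKM of at least 1 in at least 2 libraries were kept, which left 14839 of the 21258 and set 6419 aside. All 8 libraries entered 1 linear model with group means (limma 3.58.1 in R 4.3.3, limma-trend with robust moderation). The contrasts were IVF minus SCNT, KDM4E-SCNT minus SCNT and KDM4E-SCNT minus IVF. P-values were two-sided, adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Errors of log2 differences are standard errors and errors of FPKM means are standard deviations. The series design names SCNT as the control of both other groups.

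Lists of genes for 30 themes were fixed before the data were examined, as were the test, the alternative settings and the rule for named genes. For each list the members called higher, called lower and not called were counted, and the counts were repeated with p adjusted over the list alone. Lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry. Camera compares a list with all other genes, so its direction is relative to them. Fry asks whether a list's genes move one way on balance, or, in its mixed form, whether they change in either direction. The KDM4 family had 3 measured members and was not tested as a list.

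The genes named are the KDM4 family, the 10 largest rises and 10 largest falls per comparison, up to 4 members of each list with the smallest p, and, for lists of other cell types, the 3 members with the highest mean. The largest changes were taken among called genes with a symbol, a mean log2 value of at least 4 and no overlap between the groups' libraries. That minimum was written for log2 CPM and was applied to log2(FPKM + 1). Other members of a list, and single genes outside the rule, were chosen after their values were seen.

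The files hold no counts. Where a short intronless gene is covered by a single read, its FPKM shows what 1 read is worth. Among 86 olfactory receptor genes spanning 850 to 1000 bp, values from 0.13 to 0.2 FPKM were taken to be 1 read, a window that was chosen and not tested. Between 3 and 14 genes per library fell in it, with a median of 0.15 or 0.16 FPKM in every library. If the window holds, this gives at least 6.54 to 7.14 M fragments per library. The window and the spans that were chosen nearly fix this range by themselves, so it does not measure depth. Some genes that every cell uses are listed at 0 in single libraries (COX2 in IVF replicate 3 and SCNT replicates 1 and 2), so a 0 may be a failed estimate and is given only as listed.

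The scripts were tested on simulated data built from the 14839 genes with 200 changed. For IVF against SCNT, 81% of 4-fold and 10% of 2-fold changes were recovered, and 6.2% of calls were false. For KDM4E-SCNT against SCNT these shares were 55%, 5% and 4.8%, and for KDM4E-SCNT against IVF they were 57%, 3% and 13%. Small changes were thus mostly missed where only 200 genes changed. The adjusted threshold is stricter when few genes change, so these shares do not describe comparisons where many more genes were called.

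Alternatives tried were no filter on low values, a stricter filter, a pseudocount of 0.1, a fit of only the compared groups, the replicate number as a block, and leaving out each library in turn. Median-ratio, upper-quartile and quantile scaling, rescaling every library to 1 total, library weights, leaving out mitochondrially encoded genes, and leaving out KDM4E-SCNT replicate 2 together with SCNT replicate 2 were added after the data were seen. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.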

Results

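Gene expression was measured by RNA sequencing in pools of cattle embryos at the eight-cell stage. There were 3 IVF libraries, 3 SCNT libraries and 2 KDM4E-SCNT libraries. SCNT replaces the nucleus of an egg with that of a body cell, and KDM4E removes methyl groups from lysine 9 of histone H3. Sequencing depth could not be measured from these values, and 10975 to 13050 genes per library had at least 1 FPKM. The 10 most abundant genes took 15.8% to 25.7% of all FPKM. Mitochondrially encoded transcripts took 6.08%, 6.58% and 7.11% of FPKM in IVF replicates 1 to 3, 7.54%, 10.6% and 8.41% in SCNT replicates 1 to 3, and 11% and 11.5% in the KDM4E-SCNT replicates.

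The SCNT and IVF libraries stood furthest apart, and the KDM4E-SCNT libraries lay between them. Spearman's rho across genes, which are not independent replicates, was 0.885 to 0.925 between IVF libraries, 0.916 to 0.931 between SCNT libraries and 0.886 between the KDM4E-SCNT libraries. It was 0.593 to 0.679 between IVF and SCNT, 0.793 to 0.893 between IVF and KDM4E-SCNT, and 0.736 to 0.839 between SCNT and KDM4E-SCNT. The first principal component held 71.1% of the variance and placed KDM4E-SCNT replicate 1 at -5.72 and replicate 2 at 43.47, between SCNT (-119.21 to -92.39) and IVF (91.1 to 99.78).

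**Figure D1:**
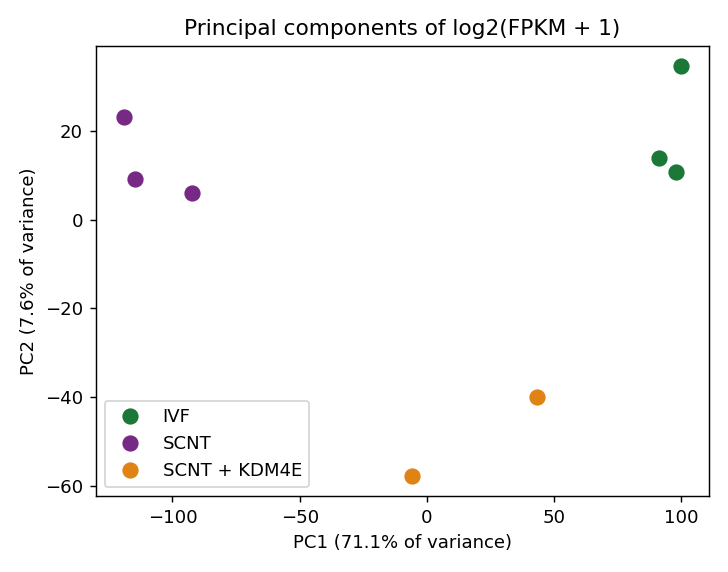
Each point is 1 library on the first (71.1% of variance) and second (7.6%) principal components of log2(FPKM + 1), coloured by group. The KDM4E-SCNT libraries (SCNT + KDM4E) lie between the SCNT and IVF libraries on the first component and below both on the second.

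The overexpressed gene was looked at first. No feature carried the symbol KDM4E, so LOC524768 (chromosome 15, 15664825 to 15668339, UMD3.1), described in the files as similar to KDM4C, was taken as the KDM4E transcript, and this identity is uncertain. It stood at 101.85 and 206.44 FPKM in the KDM4E-SCNT libraries, at 29.8 ± 4.25 FPKM (SD, n = 3) in SCNT and at 102 ± 11.9 FPKM (SD, n = 3) in IVF. It was 4.78-fold higher in KDM4E-SCNT than in SCNT (log2 difference 2.26 ± 0.34, limma adjusted p = 0.00114) and 3.36-fold higher in IVF than in SCNT (1.75 ± 0.31, adjusted p = 0.000383). KDM4E-SCNT and IVF differed by 0.51 ± 0.34 (adjusted p = 0.449). These values do not tell transcripts of the embryos' own gene from introduced ones. KDM4C (ENSBTAG00000043987.2), another member of the KDM4 family, was also lower in SCNT (8.07 ± 0.857 FPKM) than in IVF (20.7 ± 2.06 FPKM, log2 difference 1.26 ± 0.29, adjusted p = 0.00280) and than in KDM4E-SCNT (18.71 and 27.55 FPKM, 1.39 ± 0.33, adjusted p = 0.00785). The KDM4C difference from KDM4E-SCNT lost its call without KDM4E-SCNT replicate 2 (adjusted p = 0.0881), and the difference from IVF was 0.13 ± 0.33 (adjusted p = 0.870). The feature with the symbol KDM4A carries the description of another gene and is uncertain. Its differences were -0.32 ± 0.31 (IVF minus SCNT, adjusted p = 0.379), 0.31 ± 0.34 (KDM4E-SCNT minus SCNT, adjusted p = 0.508) and 0.63 ± 0.34 (KDM4E-SCNT minus IVF, adjusted p = 0.338).

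**Figure D2:**
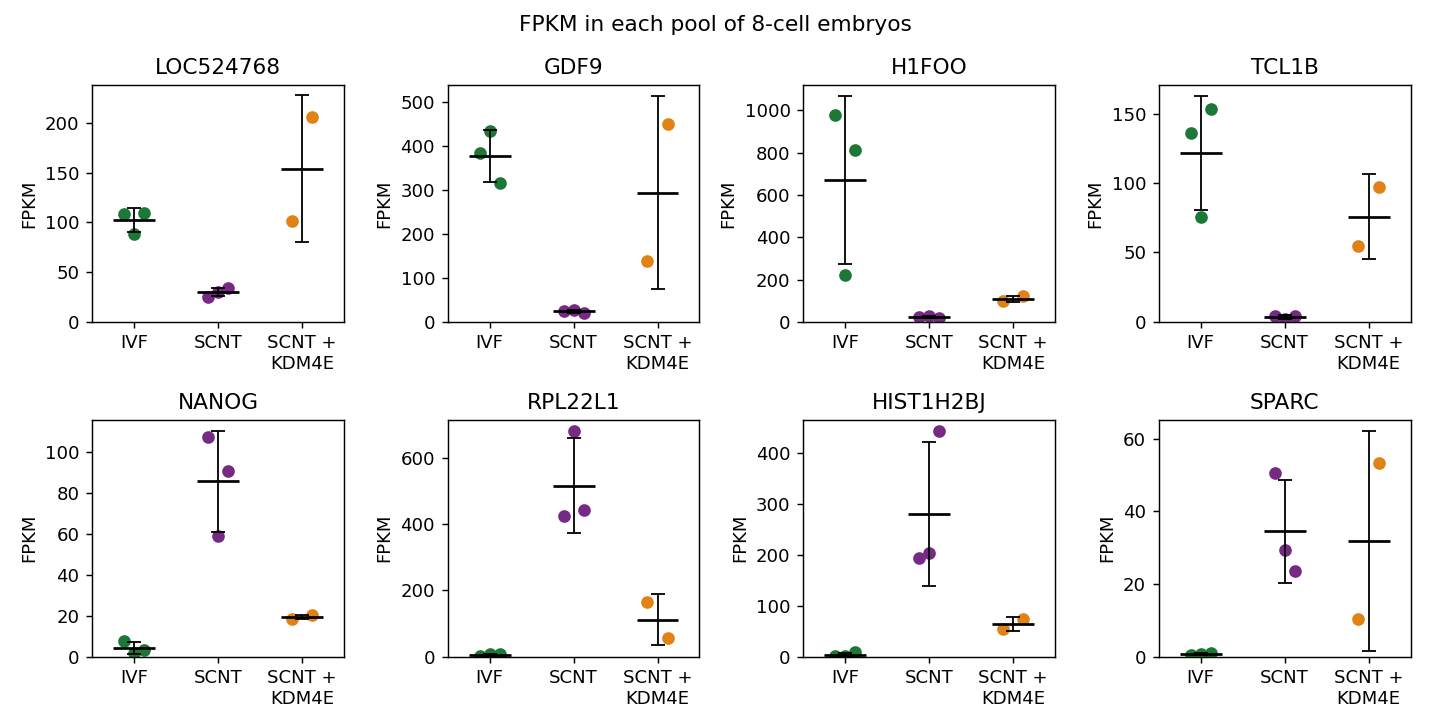
FPKM of 8 genes in each library (points, linear axes), with the group mean (line) and SD (bar). The KDM4E transcript (LOC524768) and GDF9, H1FOO and TCL1B are lowest in SCNT, while NANOG, RPL22L1 and HIST1H2BJ are highest in SCNT.

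The first comparison asked how cloned embryos differ from fertilised embryos at the same stage. Transcripts that the egg stores were far more abundant in IVF than in SCNT embryos. Of 39 measured maternal oocyte transcripts, 37 were higher in IVF and 2 did not pass the test, and the count was also 37 adjusted over the list alone. The median log2 difference was 2.88. GDF9, a growth factor of the oocyte, stood at 379 ± 59.1 FPKM in IVF and 23.9 ± 3.94 FPKM in SCNT (SD, n = 3 each), a 15.2-fold difference (log2 3.93 ± 0.38, adjusted p = 5.05e-06). The oocyte linker histone H1FOO differed by 4.57 ± 0.45, the egg-coat glycoprotein ZP2 by 3.44 ± 0.31, the oocyte gene NLRP14 by 3.17 ± 0.30 and SLBP2, an oocyte histone-mRNA binding protein, by 4.10 ± 0.34 (adjusted p = 5.92e-06, 3.71e-06, 4.68e-06 and 2.07e-06). ACCSL was higher by 3.25 ± 0.30. Other large rises were TCL1B (122 ± 41.0 against 3.60 ± 1.40 FPKM, log2 4.73 ± 0.38), the lactate dehydrogenase LDHA (3.91 ± 0.41), GDF3 (3.88 ± 0.41), INPP1 (4.18 ± 0.38), ANAPC11 (3.85 ± 0.29) and SELENBP1 (4.05 ± 0.53). CDO1, which oxidises cysteine, was listed at 305.53, 195.16 and 241.45 FPKM in IVF and at 0, 0 and 0.01 FPKM in SCNT. Camera placed the maternal list above other genes (adjusted p = 7.84e-12), with an adjusted p = 0.234 with an estimated correlation.

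Most ribosomal proteins, and smaller majorities of ribosome biogenesis, translation, nuclear oxidative phosphorylation, proteasome and splicing genes, went the other way. Of 74 measured ribosomal proteins, 71 were lower in IVF than in SCNT (71 adjusted over the list alone) and 3 did not pass, with a median log2 difference of -3.21. RPL18 stood at 15.9 ± 1.95 FPKM in IVF and 871 ± 256 FPKM in SCNT (log2 -5.66 ± 0.32, adjusted p = 2.08e-07), and RPL23 and the ribosomal protein-like RPL22L1 differed by -5.58 ± 0.31 and -6.28 ± 0.42. Of 62 ribosome biogenesis genes, 39 were lower and 4 higher (40 and 4 adjusted over the list alone, median -1.45), among them NOP16 (-4.86 ± 0.32) and NOP56 (-4.00 ± 0.34). Of 41 translation factors, 27 were lower and 2 higher (27 and 3 adjusted over the list alone, median -1.21), such as EIF1AX (-2.92 ± 0.25). Of 70 nuclear genes of oxidative phosphorylation, 45 were lower and 6 higher (46 and 7 adjusted over the list alone, median -1.66), such as the complex I subunit NDUFA5 (-5.87 ± 0.32). Of 31 proteasome genes, 20 were lower and 3 higher (20 and 3 adjusted over the list alone, median -1.35), such as PSMA2 (-5.32 ± 0.27). Of 53 splicing genes, 31 were lower and 7 higher (33 and 9 adjusted over the list alone, median -1.15), such as SRSF7 (-2.77 ± 0.25). Camera adjusted p was 2.95e-32 for ribosomal proteins, 9.26e-10 for biogenesis, 2.98e-08 for translation, 1.55e-11 for oxidative phosphorylation, 2.83e-06 for the proteasome and 2.27e-05 for splicing. With an estimated correlation the adjusted p lay between 0.229 and 0.235 for all 6. The largest falls in IVF also took in the water channel AQP11 (-6.90 ± 0.48), POP5 (-6.62 ± 0.43), TIMM10B (-6.38 ± 0.43), RNASEK (-6.00 ± 0.51), ATP23 (-6.07 ± 0.36), AGPAT5 (-6.09 ± 0.41), SSSCA1 (-6.27 ± 0.62) and the histone HIST1H2BJ (-6.38 ± 0.56), whose near-identical copies can share reads.

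Genes that embryos switch on at genome activation were mostly lower in IVF than in SCNT. Of 23 measured, 15 were lower and 3 higher (16 and 4 adjusted over the list alone), with a median of -1.48 and camera adjusted p = 0.000285 (adjusted p = 0.281 with an estimated correlation). UBTFL1 (-4.09 ± 0.47), KLF4 (-2.81 ± 0.36) and CCNA1 (-2.88 ± 0.37) were lower, and the 3 that were higher, chosen after their values were seen, were HMGN1 (1.83), SUPT4H1 (1.82) and ELF3 (1.45). Pluripotency and early lineage regulators divided. Of 25 measured, 12 were lower and 8 higher (13 and 8 adjusted over the list alone, median -0.87, camera adjusted p = 0.188). NANOG stood at 4.18 ± 3.01 FPKM in IVF and 85.6 ± 24.6 FPKM in SCNT (-4.18 ± 0.40, adjusted p = 5.08e-06). PRDM14 (-4.81 ± 0.54) and the trophectoderm regulator TEAD4 (-2.97 ± 0.36) were also lower, as was ZFP42 (-6.66 ± 0.64), which is not in the list, while POU5F1 (1.40), LIN28A (1.77) and STAT3 (2.07) were higher. X inactivation genes, 6 of 7 lower (7 adjusted over the list alone), had a median of -1.88 (camera adjusted p = 0.00237; adjusted p = 0.229 with an estimated correlation), with SMCHD1 at -2.40 ± 0.39, YY1 at -2.40 ± 0.30 and RLIM at -1.88 ± 0.33. RNA polymerase II and general transcription genes were 23 lower and 13 higher of 55 (23 and 15 adjusted over the list alone, median -0.46, camera adjusted p = 0.0461; adjusted p = 0.229 with an estimated correlation). That list call ended without IVF replicate 1 (adjusted p = 0.0610), IVF replicate 3 (0.0627) or SCNT replicate 3 (0.0560), and under quantile normalization (0.286), the stricter filter (0.170), a fit of only these groups (0.0523), 1 total per library (0.0712) or removal of mitochondrially encoded genes (0.0634), within a range of 0.0245 to 0.286 over its alternatives.

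Chromatin genes changed in both directions. Of 20 writers, readers and erasers of histone H3 lysine 9 methylation, 5 were higher in IVF and 5 lower, the same counts as adjusted over the list alone (camera adjusted p = 0.571). The methyltransferase SUV39H2 stood at 99.7 ± 14.9 FPKM in IVF and 10.7 ± 4.39 FPKM in SCNT (3.16 ± 0.32, adjusted p = 7.24e-06), and EHMT2 (1.65), SETDB1 (1.45), UHRF1 (1.42) and CBX1 (0.86) were higher as well. The demethylase KDM3A (-2.18 ± 0.35), ATF7IP (-2.39 ± 0.33), CBX5 (-1.68 ± 0.28), TRIM28 (-1.85) and SETDB2 (-1.51) were lower. Of 11 genes of DNA methylation and demethylation, 7 were higher and 3 lower, also when adjusted over the list alone (median 1.42, camera adjusted p = 0.375). DNMT3B (1.76 ± 0.33), TET2 (1.84 ± 0.32) and DPPA3 (1.79 ± 0.23) were higher, and ZFP57 (-1.82), MBD1 (-1.13) and MBD2 (-1.36) were lower. Other histone lysine methylases and demethylases were 9 lower and 5 higher of 22, as adjusted over the list alone (median -0.50, camera adjusted p = 0.178), with SETD2 (-3.81 ± 0.42), KDM6A (-3.27 ± 0.36) and EED (-2.78 ± 0.26) lower and KMT5B (2.47 ± 0.32) higher. Histone acetylation genes were 9 higher and 8 lower of 25, as adjusted over the list alone (median 0.38, camera adjusted p = 0.785), with HAT1 at -3.55 ± 0.36 and HDAC9 at 2.33 ± 0.36.

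The remaining lists did not pass the camera test in this comparison. RNA decay genes were 12 higher and 4 lower of 26, the same adjusted over the list alone (adjusted p = 0.523), with BTG4, a factor of maternal mRNA decay, at 22560 ± 4016 FPKM in IVF and 5432 ± 2283 FPKM in SCNT (2.13 ± 0.29). Glycolysis genes were 6 higher and 5 lower of 16, as adjusted over the list alone (adjusted p = 0.640), with HK2 (-3.79 ± 0.46) and PGK1 (-4.61 ± 0.32) lower. Cell cycle genes were 22 higher and 13 lower of 54 (unchanged adjusted over the list alone, adjusted p = 0.785), including AURKA (2.39 ± 0.28) and CDK1 (-2.56 ± 0.29). Genes of p53 and apoptosis were 14 higher and 7 lower of 26 (14 and 8 adjusted over the list alone, adjusted p = 0.670), and oxidative stress genes 11 higher and 5 lower of 20 (12 and 5 adjusted over the list alone, adjusted p = 0.523), with CASP6 at 2.44 ± 0.27 and NQO1 at 3.04 ± 0.33. Heat shock genes were 13 lower and 8 higher of 34 (adjusted p = 0.242), with DNAJB9 at -4.67 ± 0.41, and adhesion genes 10 higher and 4 lower of 23 (adjusted p = 0.597), with OCLN at 2.14 ± 0.32. Both counts were the same adjusted over the list alone. Interferon genes were 6 higher and 2 lower of 16 (3 and 1 adjusted over the list alone, adjusted p = 0.571), with IFIT3 at 2.17 ± 0.34. Imprinted genes were 6 lower and 5 higher of 16, as adjusted over the list alone (adjusted p = 0.571), with SNRPN at -4.63 ± 0.39 and COPG2 at 2.70 ± 0.33. Of 12 mitochondrially encoded genes, CYTB (-1.25 ± 0.22), ATP6 (-1.15 ± 0.21) and ND4L (-0.76 ± 0.23, lost without SCNT replicate 2 at adjusted p = 0.0552 and under quantile normalization at 0.242) were lower and COX3 (0.66 ± 0.22, lost without IVF replicate 3 or SCNT replicate 2 at adjusted p = 0.0656 and 0.0766, and under median-ratio or upper-quartile scaling at 0.124 and 0.162) was higher, the same 4 adjusted over the list alone (camera adjusted p = 0.193). The lower calls among the 12 became 6 under median-ratio and 7 under upper-quartile scaling, with 0 higher in limma under both. Median and camera direction differed in sign for H3K9 methylation, histone acetylation, glycolysis and blood markers, which had medians above 0 and fell below other genes.

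Markers of other cell types were measured beside these groups. Fibroblast markers were 6 lower and 3 higher in IVF of 20 (the same adjusted over the list alone, camera adjusted p = 0.190). SPARC stood at 50.59, 29.5 and 23.56 FPKM in SCNT replicates 1 to 3, at 0.52, 0.59 and 0.94 in IVF and at 10.4 and 53.32 in KDM4E-SCNT. LGALS1 stood at 42.99 to 68.96 FPKM in SCNT, 8.13 to 23.98 in IVF, and 10.94 and 127.17 in KDM4E-SCNT. Cumulus and granulosa markers were 6 higher in IVF and 1 lower of 10 (the same adjusted over the list alone, camera adjusted p = 0.255), with HAS2 at 41.84 to 70.27 FPKM in IVF and 4.87 to 9.56 in SCNT. Sperm markers were 3 higher (LDHC 3.54 ± 0.28, ZPBP 1.62 ± 0.38, TEKT1 1.64 ± 0.33) and 1 lower (CRISP2 -3.09 ± 0.36) of 9, and blood markers 3 higher (PTPRC 2.03 ± 0.44, CD3E 1.13 ± 0.39, CD14 1.03) and 2 lower (HBA -2.88 ± 0.34, HBA1 -2.87 ± 0.34) of 8, both as adjusted over the list alone (camera adjusted p = 0.571 for each). HBA and HBA1 are near copies that share reads, and the CD3E call ended without IVF replicate 3, SCNT replicate 1 or SCNT replicate 3 (adjusted p = 0.124, 0.0581 and 0.0950).

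Limma called 8680 of 14839 genes between IVF and SCNT, 58.5% of those tested, with 5182 higher and 3498 lower in IVF. The groups' libraries did not overlap for 64.4% of genes, where chance gives 10%. At least a 4-fold difference was seen for 1786 genes higher in IVF and 1565 lower. Fry's adjusted p was 0.000426 for the maternal list and for the ribosomal list.

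**Figure D3:**
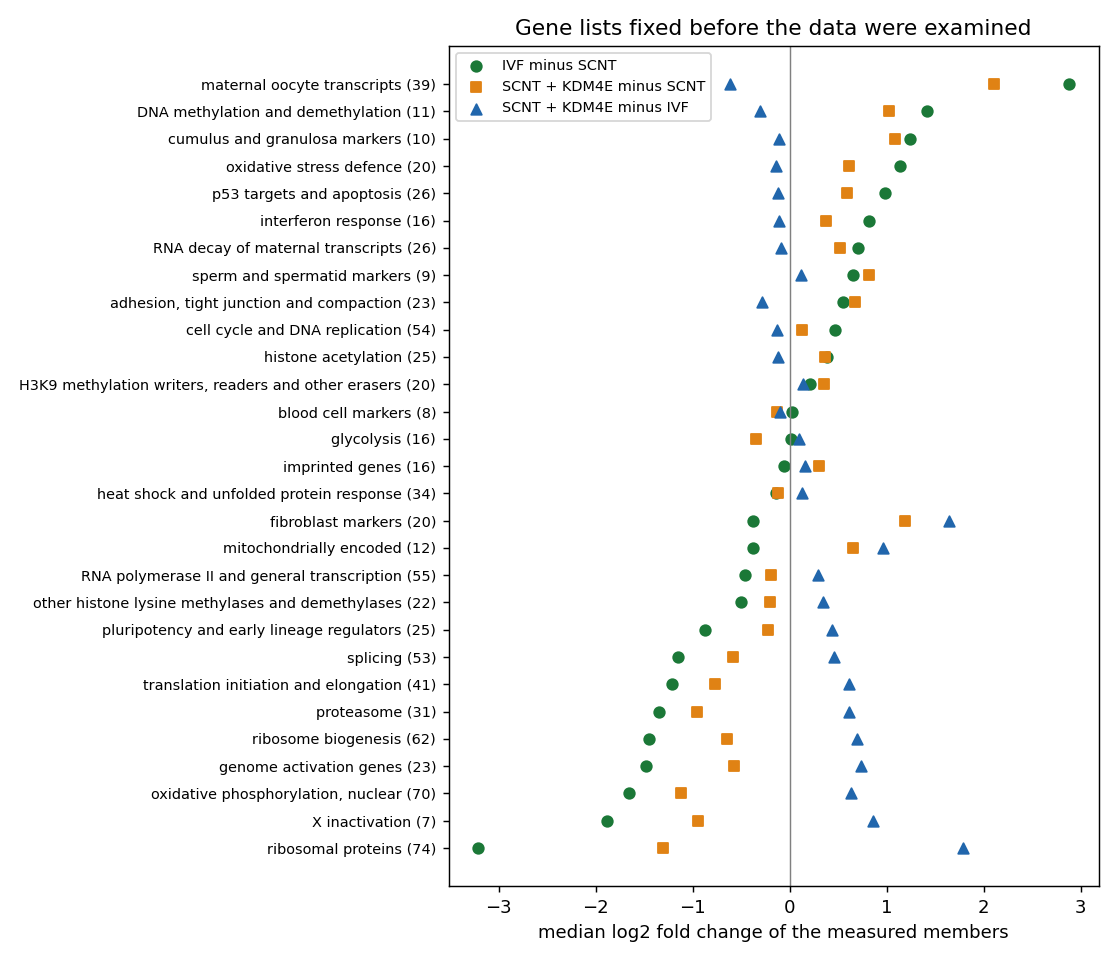
Median log2 fold change of each gene list (number of measured members in brackets) in the 3 comparisons, on a linear axis of log2 values. Maternal oocyte transcripts lie at 2.88 for IVF minus SCNT and 2.11 for KDM4E-SCNT minus SCNT, and ribosomal proteins at -3.21 and -1.31.

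The next comparison asked what KDM4E overexpression changes in cloned embryos. Maternal oocyte transcripts were higher with KDM4E than in SCNT without it. Of 39, 37 rose and 2 did not pass (37 adjusted over the list alone), with a median log2 difference of 2.11. GDF9 stood at 138.44 and 450.31 FPKM against 23.9 ± 3.94 FPKM in SCNT (3.34 ± 0.42, adjusted p = 0.000615), ZP2 rose by 2.89 ± 0.35 and NLRP14 by 2.57 ± 0.34 (adjusted p = 0.000577 and 0.000666). SLBP2 rose by 3.65 ± 0.38 and TCL1B by 4.06 ± 0.42. The largest rises also held GDF3 (3.34 ± 0.45), INPP1 (3.35 ± 0.43), the retinaldehyde dehydrogenase ALDH1A1 (3.81 ± 0.39), MDGA1 (3.90 ± 0.39), ZNF2 (3.34 ± 0.39) and the dynein chain DYNC1I1 (3.33 ± 0.49). CDO1, listed at 0, 0 and 0.01 FPKM in SCNT, stood at 59.05 and 149.84 FPKM. Camera adjusted p for the maternal list was 6.81e-13 (adjusted p = 0.338 with an estimated correlation).

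Most ribosomal proteins fell with KDM4E, while most translation, ribosome biogenesis and splicing genes did not pass. Ribosomal proteins fell for 58 of 74 and 16 did not pass (66 fell and 2 rose adjusted over the list alone, median -1.31), with RPL18 at 284.31 and 140.23 FPKM against 871 ± 256 FPKM (-2.08 ± 0.36, adjusted p = 0.00182) and RPS15 at -2.08 ± 0.35. Translation factors fell for 18 of 41 (19 adjusted over the list alone, median -0.77), and ribosome biogenesis genes fell for 16 and rose for 2 of 62 (15 and 2 adjusted over the list alone, median -0.65), such as NOP56 (-2.37 ± 0.38). Nuclear oxidative phosphorylation genes fell for 32 and rose for 2 of 70 (37 and 2 adjusted over the list alone, median -1.12), such as NDUFA5 (-2.27 ± 0.36), and proteasome genes fell for 15 and rose for 2 of 31 (19 and 2 adjusted over the list alone, median -0.96), such as PSMA2 (-2.05 ± 0.30). Splicing genes fell for 11 and rose for 4 of 53, as adjusted over the list alone (median -0.58), such as SRSF7 (-1.93 ± 0.28). Camera adjusted p was 4.19e-25, 6.59e-08, 1.15e-06, 1.00e-11, 1.82e-06 and 0.00074 in that order, and with an estimated correlation the adjusted p was 0.338, 0.338, 0.365, 0.338, 0.338 and 0.432. The splicing call ended under quantile normalization (adjusted p = 0.213, range 3.73e-05 to 0.213). The 10 largest falls held C23H6orf62 (-3.52 ± 0.37), RESTA (-3.50 ± 0.41), the glycine cleavage protein GCSH (-3.28 ± 0.55), the transcription factor TCF7L2 (-2.97 ± 0.36), AGPAT5 (-2.93 ± 0.46), AQP11 (-2.86 ± 0.54), SNAP25 (-2.81 ± 0.39), PRPS1 (-2.75 ± 0.42), the mitochondrial ribosomal protein MRPL27 (-2.73 ± 0.28) and C13H20orf24 (-2.68 ± 0.39).

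Genome activation genes fell for 5 and rose for 2 of 23 (8 and 3 adjusted over the list alone, median -0.57, camera adjusted p = 0.0131; adjusted p = 0.487 with an estimated correlation). That call ended without KDM4E-SCNT replicate 2 (adjusted p = 0.263), without it and SCNT replicate 2 (0.156) and under quantile normalization (0.155), within a range of 0.000695 to 0.263. EIF1AX fell by 1.18 ± 0.28 and SUPT4H1 rose by 1.36 ± 0.40. The EIF1AX call ended under quantile normalization (limma adjusted p = 0.1), and that of SUPT4H1 under median-ratio or upper-quartile scaling (0.0589 and 0.0718). Both calls ended without KDM4E-SCNT replicate 2 (adjusted p = 0.0856 and 0.0688) and that of SUPT4H1 also without KDM4E-SCNT replicate 1 or SCNT replicates 2 or 3 (0.0987, 0.0649 and 0.0708). Pluripotency regulators fell for 6 and rose for 6 of 25 (9 and 7 adjusted over the list alone, camera adjusted p = 0.318), with NANOG at 18.53 and 20.14 FPKM against 85.6 ± 24.6 FPKM (-2.05 ± 0.45, adjusted p = 0.00543) and KRT8 higher by 2.03 ± 0.41. In the X inactivation list SMCHD1 (-1.61 ± 0.43) and YY1 (-1.18 ± 0.34) fell, of 7 (3 adjusted over the list alone, camera adjusted p = 0.0283; adjusted p = 0.338 with an estimated correlation). Without KDM4E-SCNT replicate 2 the list call (adjusted p = 0.147, range 0.0143 to 0.164) and both genes' calls (0.109 and 0.158) ended, and that of YY1 also without SCNT replicate 3 (0.0610). The list call ended with the stricter filter too (0.0579). LBR was called lower with the stricter filter (0.0380), without KDM4E-SCNT replicate 1 (0.0106) and under median-ratio, upper-quartile and quantile scaling (0.0233, 0.0233 and 0.0425).

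In the H3K9 methylation list 2 genes rose and 3 fell of 20, as adjusted over the list alone (camera adjusted p = 0.651). SUV39H2 stood at 56.54 and 71.76 FPKM against 10.7 ± 4.39 FPKM (2.54 ± 0.36, adjusted p = 0.000847), SETDB1 rose by 1.47 ± 0.38, KDM3A fell by 1.84 ± 0.39, TRIM28 fell by 1.47 ± 0.39, and SUZ12, of the other lysine methylases, fell by 2.38 ± 0.46. SETDB1 and TRIM28 lost their calls without KDM4E-SCNT replicate 2 (adjusted p = 0.107 and 0.108), TRIM28 also without SCNT replicate 1 (0.0582). DNA methylation genes rose for 5 and fell for 1 of 11 (7 and 2 adjusted over the list alone, camera adjusted p = 0.276), among them DPPA3 (1.48 ± 0.26), DNMT3B (1.45 ± 0.37) and TET2 (1.32 ± 0.35). The calls of DNMT3B and TET2 ended without KDM4E-SCNT replicate 2 (adjusted p = 0.0899 and 0.0848). Other lysine methylases fell for 4 and rose for 3 of 22 (5 and 3 adjusted over the list alone, adjusted p = 0.276), and acetylation genes rose for 8 and fell for 6 of 25, as adjusted over the list alone (adjusted p = 0.719).

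Of 12 mitochondrially encoded genes 5 rose (ND1 0.67, ND2 0.84, ND3 1.36, ND5 0.89 and COX3 1.49), the same count adjusted over the list alone. Camera gave adjusted p = 0.168, 0.0190 under quantile normalization and 0.0309 without both KDM4E-SCNT replicate 2 and SCNT replicate 2, within a range of 0.0190 to 0.476. ND2 and ND5 lost their calls without KDM4E-SCNT replicate 2, SCNT replicate 1 or SCNT replicate 3 (adjusted p = 0.0714, 0.0533 and 0.0629 for ND2, and 0.149, 0.0771 and 0.0700 for ND5), and under median-ratio or upper-quartile scaling (0.107 and 0.154 for ND2, and 0.117 and 0.155 for ND5). The 5 calls became 2 higher without KDM4E-SCNT replicate 2, SCNT replicate 1 or SCNT replicate 3, and 2 higher and 1 lower under median-ratio or upper-quartile scaling. The mitochondrial share of FPKM was 11% and 11.5% in KDM4E-SCNT against 7.54% to 10.6% in SCNT, where COX2 at 0 may lower the shares of replicates 1 and 2. Fibroblast markers rose for 6 of 20 (VIM 2.31, S100A4 2.55, FBN1 1.79, PRRX1 1.70, CAV1 1.77 and FSTL1 1.64) and CTGF fell (-1.35), as adjusted over the list alone (camera adjusted p = 0.276). The FBN1 call ended without KDM4E-SCNT replicate 2 (adjusted p = 0.109) or SCNT replicate 1 (0.0518), and that of S100A4 with a pseudocount of 0.1 (0.0810). TIMP1 stood at 5.02 and 135.01 FPKM in KDM4E-SCNT replicates 1 and 2. Cumulus markers rose for 4 of 10 (4 adjusted over the list alone, adjusted p = 0.168), including HAS2 (2.29 ± 0.39), and sperm markers rose for 2 (LDHC 2.83 ± 0.31 and TEKT1 1.5 ± 0.37) and fell for 1 (CRISP2 -2.55 ± 0.41) of 9 (the same adjusted over the list alone, adjusted p = 0.500). The 8 blood markers did not pass (HBA -0.69 ± 0.38, adjusted p = 0.170), also adjusted over the list alone, but HBA and HBA1 were called lower under upper-quartile scaling (0.0466 and 0.0451) and CD68 without SCNT replicate 3 (0.0123).

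The other lists did not pass camera. RNA decay genes rose for 7 and fell for 2 of 26 (adjusted p = 0.498), with BTG4 at 1.74 ± 0.32. RNA polymerase II genes rose for 11 and fell for 9 of 55 (adjusted p = 0.251), heat shock genes rose for 4 and fell for 6 of 34 (0.276), oxidative stress genes rose for 6 and fell for 1 of 20 (0.494), cell cycle genes rose for 8 and fell for 3 of 54 (0.790) and interferon genes rose for 2 of 16 (0.651). All 6 counts were the same adjusted over the list alone. Imprinted genes rose for 4 and fell for 2 of 16 (5 and 3 adjusted over the list alone, 0.847), glycolysis genes rose for 6 and fell for 3 of 16 (6 and 4, 0.651), p53 and apoptosis genes rose for 9 and fell for 4 of 26 (10 and 5, 0.651) and adhesion genes rose for 6 and fell for 3 of 23 (8 and 3, 0.651), the pairs in brackets being adjusted over the list alone. Examples are GSR (1.69 ± 0.31), PGK1 (-1.96 ± 0.35), LDHA (3.02 ± 0.46), CASP6 (2.13 ± 0.30), COPG2 (2.27 ± 0.37) and AURKA (1.67 ± 0.31). Camera placed H3K9 methylation, acetylation, imprinted and cell cycle genes below other genes although their medians and means were above 0, and glycolysis had a median of -0.35 and a mean of 0.24.

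Limma called 4844 genes between KDM4E-SCNT and SCNT, 3208 higher and 1636 lower, and the libraries did not overlap for 59.5% of genes, where chance gives 20%. The share of higher calls, 66.2%, moved to 50.9% under median-ratio, 49.2% under upper-quartile and 49.8% under quantile scaling. Without KDM4E-SCNT replicate 2 the count was 1575, and without it and SCNT replicate 2 it was 1608. Fry's adjusted p was 0.00719 for the maternal list and 0.0127 for the ribosomal list.

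Most genes called between KDM4E-SCNT and SCNT were also called between IVF and SCNT, while about as many of the IVF calls were not shared as were. Of the 3208 genes higher in KDM4E-SCNT than in SCNT, 2967 (92.5%) were also higher in IVF, and of the 1636 lower, 1586 (96.9%) were also lower in IVF. These made up 57.3% of the 5182 genes higher and 45.3% of the 3498 genes lower in IVF than in SCNT. GDF9, ZP2, SLBP2, TCL1B and SUV39H2 were among the shared rises, and RPL18, NDUFA5, PSMA2, NANOG and KDM3A among the shared falls. Independent lists of these sizes would share 1120 and 386 genes, and unchanged groups simulated against the same SCNT libraries shared at most 1 gene in 100 simulations. Unchanged groups give few calls of any kind, so that low count was built in. The log2 differences correlated across genes at r = 0.88 (simulated 0.45), with a covariance of 1.69 against a simulated 0.07. The 3 SCNT libraries were not split between the 2 comparisons, so part of the excess may come from the shared controls. Without KDM4E-SCNT replicate 2 the shared counts were 1000 higher and 454 lower, and the lower count was 973 without SCNT replicate 1 and 1022 without SCNT replicate 3. Only 6 genes were lower in IVF and higher in KDM4E-SCNT than in SCNT, among them S100A4, chosen after its values were seen, and limma found 0 the other way round (6631 and 9456 genes had an unadjusted p under 0.05 in the respective comparisons with SCNT).

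**Figure D4:**
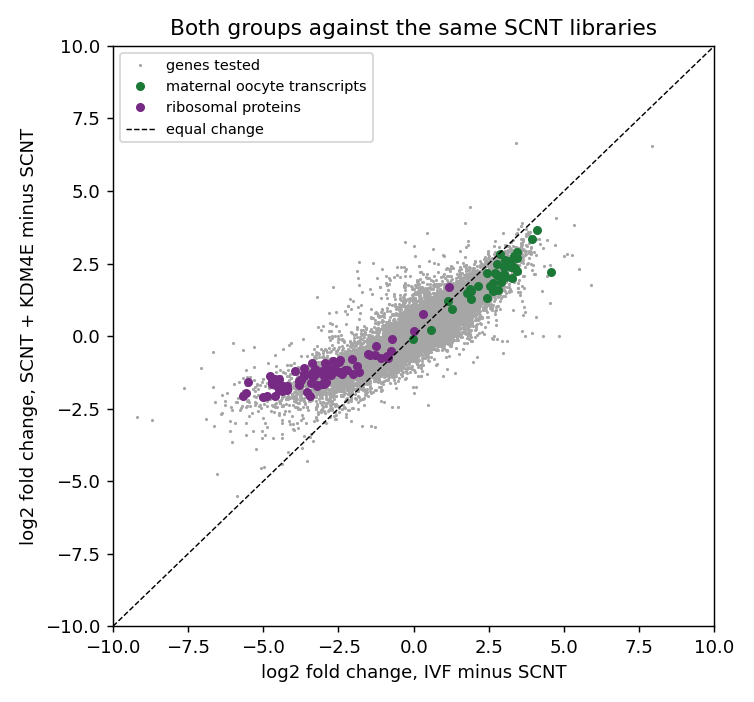
Log2 fold change of each gene tested for KDM4E-SCNT minus SCNT against that for IVF minus SCNT, with maternal oocyte transcripts and ribosomal proteins coloured and a dashed line of equal change. The 2 sets of values share the SCNT libraries and correlate at r = 0.88, and ribosomal proteins lie nearer to 0 on the vertical axis (median -1.31) than on the horizontal one (median -3.21).

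The last comparison set KDM4E-SCNT beside IVF embryos. Most ribosomal proteins were higher in KDM4E-SCNT than in IVF, while most genes of the other protein synthesis lists did not pass. Of 74 ribosomal proteins, 58 were higher and 16 did not pass (66 higher adjusted over the list alone, median 1.79), such as RPL18 (3.58 ± 0.36, adjusted p = 0.000123), RPL23 (3.64 ± 0.35) and RPL34 (3.95 ± 0.35). Nuclear oxidative phosphorylation genes were higher for 23 of 70 (26 adjusted over the list alone, median 0.63), ribosome biogenesis genes for 12 of 62 (25, median 0.69), translation factors for 7 of 41 (11, median 0.61), splicing genes for 6 of 53 (9, median 0.46) and proteasome genes for 6 of 31 (10, median 0.61), the counts in brackets being adjusted over the list alone. Camera adjusted p was 1.15e-45 for ribosomal proteins, 6.28e-08, 1.65e-09, 3.70e-05, 5.72e-05 and 0.000102 for the others in that order. With an estimated correlation the adjusted p was 0.284 for the proteasome and 0.261 for the other 5. NDUFA5 (3.60 ± 0.36), NOP16 (3.25 ± 0.36), PSMA2 (3.27 ± 0.30) and PSMA1 (3.79 ± 0.43) were among them.

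Maternal oocyte transcripts had a median of -0.61 in KDM4E-SCNT against IVF. Camera placed the list below other genes (adjusted p = 1.36e-07; adjusted p = 0.284 with an estimated correlation), but fry did not pass (adjusted p = 0.0821). Of 39, 2 passed, H1FOO (-2.35 ± 0.50, adjusted p = 0.0126) and ZAR1L (-1.20 ± 0.33, adjusted p = 0.0479), and 1 did so adjusted over the list alone. Genome activation genes were higher for 7 of 23 (10 adjusted over the list alone, median 0.74, camera adjusted p = 7.49e-05; adjusted p = 0.261 with an estimated correlation), including EIF1AX (1.74 ± 0.28), KLF4 (1.72 ± 0.41) and UBTFL1 (2.64 ± 0.53). Pluripotency regulators were higher for 5 of 25 (8 adjusted over the list alone, camera adjusted p = 0.0809), among them NANOG (2.13 ± 0.45, adjusted p = 0.0117) and PRDM14 (3.31 ± 0.60), while ZFP42 (4.91 ± 0.72), also higher, is not in that list. That list passed with the replicate block (adjusted p = 0.0407) and without KDM4E-SCNT replicate 2 (0.0386), within a range of 0.0386 to 0.306. RNA polymerase II genes were higher for 9 of 55 (11 adjusted over the list alone, camera adjusted p = 0.00862; adjusted p = 0.261 with an estimated correlation), such as POLR2G (1.40 ± 0.27), and X inactivation genes had a median of 0.86 with none of 7 past the test (2 adjusted over the list alone, camera adjusted p = 0.00457; adjusted p = 0.261 with an estimated correlation). Both list calls ended without KDM4E-SCNT replicate 1 (adjusted p = 0.163, range 0.00267 to 0.163, and 0.0646, range 0.00127 to 0.0646), and that of RNA polymerase II genes also with the stricter filter (0.0569). In the X inactivation list YY1 passed without IVF replicate 2 (0.0237) or KDM4E-SCNT replicate 2 (0.0493), with the stricter filter (0.0352) and with library weights (0.0241), RLIM without KDM4E-SCNT replicate 2 (0.0394), with the stricter filter (0.0476) and with the replicate block (0.0427), and LBR without KDM4E-SCNT replicate 2 (0.0492). The single-gene calls of H1FOO, ZAR1L, KLF4, UBTFL1, PRDM14, NANOG and POLR2G also ended without KDM4E-SCNT replicate 1 (0.142, 0.304, 0.314, 0.178, 0.117, 0.0997 and 0.0849). H1FOO lost its call without IVF replicate 3 too (0.0552), KLF4 without IVF replicates 1 or 3 (0.0508 and 0.0781), NANOG without KDM4E-SCNT replicate 2 (0.0518), and ZAR1L without any single library except IVF replicate 2 (0.0640 to 0.304) and with the replicate block (0.0788).

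Some mitochondrially encoded transcripts and some fibroblast markers were higher in KDM4E-SCNT than in IVF. Of 12 mitochondrially encoded genes 5 passed (11 adjusted over the list alone, median 0.96, camera adjusted p = 2.98e-07; adjusted p = 0.261 with an estimated correlation), with ND1 at 1.06 ± 0.24 (adjusted p = 0.0171). The single-gene calls depended on the libraries: limma called 0 of the 12 without IVF replicate 1 or without KDM4E-SCNT replicate 1, 1 without SCNT replicate 3, 2 without IVF replicate 2, IVF replicate 3 or KDM4E-SCNT replicate 2, 3 without SCNT replicate 1, and 1 under quantile normalization. ND1 was at adjusted p = 0.0853 without IVF replicate 1 and 0.0849 without KDM4E-SCNT replicate 1, and COX1 at 0.109 and 0.0767. The list itself passed camera under every alternative run (adjusted p at most 4.62e-05). The mitochondrial share of FPKM was 11% and 11.5% against 6.08% to 7.11% in IVF, where COX2 at 0 may lower the share of replicate 3. Of 20 fibroblast markers 8 passed (10 adjusted over the list alone, median 1.64, camera adjusted p = 2.93e-05, and 0.315 with an estimated correlation): VIM (2.57), LUM (3.85), S100A4 (4.38), SPARC (3.89), TIMP1 (4.36), PRRX1 (1.76), CAV1 (2.08) and CTGF (1.89). Fry did not pass for the fibroblast list (adjusted p = 0.0516). The CTGF call ended without either KDM4E-SCNT library (adjusted p = 0.0723 and 0.0537). The list call ended without KDM4E-SCNT replicate 2 (adjusted p = 0.0557, range 3.03e-09 to 0.0951), where LUM stood at 84.6 FPKM against 13.38 FPKM in replicate 1. The largest single rises were RNASEK (5.74 ± 0.57), TMSB4 (5.19 ± 0.49, a gene with near copies and so uncertain), S100A4 (4.38 ± 0.51), HIST1H2BJ (4.36 ± 0.62), POP5 (4.36 ± 0.48), FOLR1 (4.33 ± 0.55), PNP (4.21 ± 0.65), SELENOS (4.12 ± 0.40), AQP11 (4.04 ± 0.54) and SSSCA1 (4.03 ± 0.69, lost without KDM4E-SCNT replicate 1 at adjusted p = 0.0727). Among the 92 falls, of which 39 were at least 4-fold, were CRLF3 (-1.24 ± 0.32) and catalase, CAT (-1.10 ± 0.30). Both lost their calls without any single library except SCNT replicate 2 (adjusted p = 0.0521 to 0.159 and 0.0660 to 0.213), and CAT also with the replicate block (0.0839).

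Neither the 20 H3K9 methylation genes nor the 11 DNA methylation genes held a call between KDM4E-SCNT and IVF, in limma over all genes or adjusted over the list alone, in a comparison where 2920 genes had an unadjusted p under 0.05. The medians were 0.14 and -0.31 (camera adjusted p = 0.752 and 0.744), while fry's mixed test, which takes changes in both directions, passed for both lists (adjusted p = 0.0148 and 0.0132). That mixed test also passed for most other lists in this comparison, so it does not single these out. ATF7IP (1.29, adjusted p = 0.0582) was called with the replicate block (0.0368), with the stricter filter (0.0396) and without IVF replicate 3 (0.0274), and ZFP57 (adjusted p = 0.0968) without KDM4E-SCNT replicate 2 (0.0426). Other lysine methylases were higher for 3 of 22 (4 adjusted over the list alone, adjusted p = 0.105), namely SETD2 (2.31 ± 0.47), KDM6A (1.59 ± 0.40) and EED (1.47 ± 0.29), and acetylation genes for 3 of 25, as adjusted over the list alone (adjusted p = 0.943), namely HAT1 (2.33 ± 0.40), SIRT1 (1.93 ± 0.34) and KAT2B (1.91 ± 0.42). These 6 calls ended without KDM4E-SCNT replicate 1 (adjusted p from 0.0582 for EED to 0.339 for KDM6A), that of KDM6A also without IVF replicates 2 or 3 or SCNT replicates 1 or 3 (0.0502 to 0.0809). The other lysine methylases list passed without KDM4E-SCNT replicate 2 (0.0386), without it and SCNT replicate 2 (0.0418) and with the stricter filter (0.0397, range 0.0386 to 0.522). Imprinted genes were higher for 3 of 16 (SNRPN 2.29 ± 0.43, NDN 2.66 ± 0.42 and SNU13 1.24 ± 0.28, adjusted p = 0.559), blood markers for 2 of 8 (HBA 2.19 ± 0.38 and HBA1 2.17 ± 0.37, 0.858), glycolysis genes for 2 of 16 (HK2 2.42 ± 0.52 and PGK1 2.65 ± 0.35, 0.752), p53 and apoptosis genes for 2 of 26 (GADD45A 1.25 ± 0.33 and DIABLO 2.68 ± 0.57, 0.937), heat shock genes for 1 of 34 (DNAJB9 2.65 ± 0.46, 0.471), cell cycle genes for 1 of 54 (CDK1 1.78 ± 0.32, 0.444) and interferon genes for 1 of 16 (IRF3 2.12 ± 0.45, 0.765). Oxidative stress genes were higher for 2 of 20 (TXN 2.25 ± 0.45 and TXN2 1.87 ± 0.43) and lower for CAT (0.744). These 8 counts were the same adjusted over the list alone. Without KDM4E-SCNT replicate 1 the calls of SNRPN, SNU13, HK2, GADD45A, DIABLO, DNAJB9, CDK1, IRF3, TXN and TXN2 ended (adjusted p from 0.0762 for CDK1 to 0.424 for GADD45A). That of GADD45A also ended without any IVF library or SCNT replicates 1 or 3 (0.0589 to 0.111) and with the replicate block (0.0857), and that of TXN2 without IVF replicate 2 (0.0538). RNA decay genes (26) had a camera adjusted p = 0.896. Cumulus (10 genes, 0.744), sperm (9, 0.765) and adhesion genes (23, 0.744) held no call, also adjusted over the list alone. Of the adhesion genes, F11R was called with the replicate block (0.0196), with the stricter filter (0.0449) and without IVF replicate 3 (0.0191), and CLDN6 without IVF replicate 2 (0.0366) or SCNT replicate 1 (0.0404). The cell cycle gene PCNA was called with the replicate block (0.0390), with the stricter filter (0.0363) and without KDM4E-SCNT replicate 2 (0.0275). Medians and camera directions, or medians and means, differed in sign for DNA methylation, acetylation, RNA decay, sperm, blood, p53, interferon and adhesion genes.

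Limma called 967 genes between KDM4E-SCNT and IVF, 875 higher and 92 lower in KDM4E-SCNT, and the libraries did not overlap for 33.9% of genes, where chance gives 20%. The count was 291 without KDM4E-SCNT replicate 1 and 629 when only these groups were fitted. Fry's adjusted p was 0.00784 for the ribosomal list.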

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

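The tests chosen only after the data were seen were the 4 other scalings, library weights, leaving out mitochondrially encoded genes, and leaving out KDM4E-SCNT replicate 2 together with SCNT replicate 2. The alternatives in the plan that need read counts (median-ratio or upper-quartile size factors on counts, another count test and voom weights) were not run because the values are FPKM.

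The IVF against SCNT count stayed within 1.5 times its value under all alternatives run and was 7264 to 8822 with a library left out. For KDM4E-SCNT against SCNT the range with a library left out was 1575 (without KDM4E-SCNT replicate 2) to 5251, and for KDM4E-SCNT against IVF it was 291 (without KDM4E-SCNT replicate 1) to 1287. Leaving out a KDM4E-SCNT library leaves 1, which is then assumed to vary like the other groups. Fewer samples may lower the counts, but the highest count against IVF was also reached with 1 such library, without KDM4E-SCNT replicate 2. The calls shared by both comparisons with SCNT were 1000 to 3060 higher and 454 to 1689 lower, with 973 and 1022 lower without SCNT replicates 1 and 3. Without both KDM4E-SCNT replicate 2 and SCNT replicate 2 the counts were 1608 for KDM4E-SCNT against SCNT, and 1066 higher and 446 lower shared. Fitting only the compared groups gave 629 calls for KDM4E-SCNT against IVF, and there the cause was not tested. The KDM4E transcript (LOC524768) kept its call under every alternative run, at 1.75 to 2.76 with a library left out and an adjusted p of at most 0.0209. Lists past the camera test numbered 9 to 10, 7 to 9 and 10 to 13 in the 3 comparisons with a library left out.

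Relative to the deposited scale, the median of all genes in IVF against SCNT moved by -0.18 under median-ratio, -0.19 under upper-quartile and -0.21 under quantile scaling, and by 0.15 with 1 total per library. In KDM4E-SCNT against SCNT it moved by -0.20, -0.24, -0.31 and 0.09. Of the genes named, 131 of 135 kept their direction and their side of the threshold under all alternatives run in IVF against SCNT, 77 of 136 in KDM4E-SCNT against SCNT and 67 of 129 in KDM4E-SCNT against IVF. In KDM4E-SCNT against SCNT, KDM3A, KRT8, PGK1, S100A4, SNRPN, SUZ12 and TEKT1 were among those that lost their calls when KDM4E-SCNT replicate 2 and SCNT replicate 2 were both left out. Changes of sign were few and all in genes without a call. In KDM4E-SCNT against IVF, KDM4C was -0.13 without KDM4E-SCNT replicate 2 (also with SCNT replicate 2 out) and 0.40 without replicate 1, and PTGS2 was 0.54 without KDM4E-SCNT replicate 1 and -1.57 without replicate 2. In KDM4E-SCNT against SCNT, KDM4A was 0.00 under upper-quartile and -0.01 under quantile scaling. The cause of these was not tested.

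The labels give the groups the same replicate numbers but do not say that they mark pairs. Any sign of pairing in the values was weak, so the libraries were not treated as pairs. Deviations of same-numbered libraries correlated at 0.01 to 0.12 over 7 pairs, all above 0 (1 of them over 0.1), and those of the other 14 pairs at -0.13 to 0.13. Deviations sum to 0 within a group, so these correlations are not independent, and a weak pairing stays open. With the replicate block, 8656, 4252 and 957 genes were called in the 3 comparisons, and the KDM4E transcript differed by 2.33. The lists numbered 10, 9 and 13. Not every library correlated best with its own number. Depth may limit low genes, but it could not be measured, since the window taken as 1 read nearly fixes its own estimate. Of 100 simulated 2-fold changes 10, 5 and 3 were found in the 3 comparisons, in simulations with only 200 changed genes.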

Other observations

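The tests in this part chosen only after the result was seen were those of fibroblast RNA, exchanged labels, a later place in the switch, both mixture models, the equal shift, the genes above both groups, the histone sets, fibroblast-type cells, the gene families and the histone count.

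Some replication-dependent histone genes were higher in KDM4E-SCNT than in IVF, in SCNT or in both. Of 25 genes with the prefix HIST, 9 were higher than in IVF (median log2 difference 1.17, camera adjusted p = 3.63e-07; adjusted p = 0.266 with an estimated correlation) and 12 were higher and 1 lower than in SCNT (median 1.12, adjusted p = 0.0165; adjusted p = 0.516 with an estimated correlation). Between IVF and SCNT 7 were higher and 6 lower (median -0.01, which was -0.28 to 0.18 over the other scalings). The other directions held under all 4 other scalings (medians 1.08 to 1.13 and 0.81 to 1.22). HIST1H2AG stood at 498.03 and 310.99 FPKM in KDM4E-SCNT, 89.02 to 237.44 FPKM in IVF and 64.38 to 136.87 FPKM in SCNT, and HIST1H2BM at 15.95 and 35.75, 0.9 to 6.65 and 4.2 to 5.65 FPKM. The linker histone HIST1H1A stood at 383.59 and 433.21 FPKM against 43.07 to 66 FPKM in SCNT (log2 2.86, adjusted p = 0.000422), and differed from IVF by 0.39 (adjusted p = 0.536). HIST1H2BJ, H2AFV and H3F3B were lower than in SCNT (log2 -2.02, -1.37 and -1.24). Of the 55 genes that passed both single tests as higher in KDM4E-SCNT, 12 are histones by symbol or description (21.8%, against 97 of 14839 tested, 0.654%; two-sided Fisher's exact test across genes, which are not independent, p = 1.05e-15). That count was chosen after the result was seen, so its p is not evidence. Histone genes have near-identical copies that share reads, so single values are uncertain and the 12 may hold fewer separate signals. In a joint test of lying above both groups, limma called 0 genes (lowest adjusted p = 0.0596).

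Among 24 gene sets, taken by symbol prefix except for the X-linked genes, mitochondrial ribosomal proteins had medians below 0 in IVF and in KDM4E-SCNT against SCNT, under all 4 other scalings too. MRPL genes were 25 lower and 5 higher of 47 in IVF (median -1.10, adjusted p = 6.77e-06; adjusted p = 0.302 with an estimated correlation) and 20 lower and 2 higher in KDM4E-SCNT (median -0.86, adjusted p = 1.47e-07; adjusted p = 0.327 with an estimated correlation). RAB genes of vesicle traffic were 28 higher and 4 lower of 57 in IVF, a direction kept under all 4 other scalings in both comparisons (median 0.85, adjusted p = 0.0255; adjusted p = 0.302 with an estimated correlation) and 20 higher and 2 lower in KDM4E-SCNT (median 0.95, adjusted p = 0.0289; adjusted p = 0.327 with an estimated correlation). The 746 X-linked genes had a median of -0.11 in IVF against SCNT, where autosomal genes had 0.42 (camera adjusted p = 0.0255, and 0.302 with an estimated correlation). With 1 total per library the X-linked median was 0.01 and the autosomal median 0.58, though 1 factor per library can hardly change that gap. Under quantile normalization the X-linked median was -0.32 and the autosomal median 0.2. In KDM4E-SCNT against IVF 90 X-linked genes were higher and 5 lower, a direction kept under all 4 other scalings (median 0.23, autosomal -0.04, adjusted p = 0.00618; adjusted p = 0.266 with an estimated correlation).

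SCNT libraries held fewer maternal and more ribosomal transcripts than IVF libraries. Scaling of the values is argued against, since over 4 other scalings each list's median stayed at least 2.45 log2 units from that of all genes, in opposite directions. RNA of fibroblast-type cells is argued against as well, since fibroblast markers rose by 76.5 FPKM in all, 0.104% of the 73413 FPKM by which ribosomal proteins rose. A candidate explanation is that the SCNT embryos were further through the switch from maternal to embryonic transcripts, which fits 15 genome activation genes being lower in IVF, though collection time, poly(A) tail length and an effect of cloning were not separated. An exchange of the IVF and SCNT labels stays open, because IVF stood apart from both cloned groups in 902 genes and SCNT apart from both others in 4553, and neither count tells which group was fertilised.

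The KDM4E-SCNT libraries lay between SCNT and IVF. Independent noise in the shared SCNT libraries is argued against as the whole cause, since it gave a simulated covariance of 0.07 where 1.69 was seen. The simulated overlap of at most 1 call, against 2967 and 1586, decides nothing, as unchanged groups give few calls. An offset common to all 3 SCNT libraries was not simulated and stays open. An equal partial shift of all genes without a library offset is argued against narrowly, since genes higher and lower in IVF differed by 0.11 to 0.3 in how far they had moved over all scalings and left-out libraries (bound 0.1), but with a free offset it stays open, at a gap of 0.31 to 0.35 log2 in replicate 1 and 0.19 to 0.22 in replicate 2 (bound 0.25). A mixture of IVF-like and SCNT-like embryos in a pool was tried without and with a free offset per library. The offset and all bounds were set after the first version was seen. Without an offset, shares from both kinds of gene differed by 22.4 points in replicate 1 and 10.2 in replicate 2. In replicate 2 the difference was 6.2 without IVF replicate 1, and within the bound of 10 points also without SCNT replicate 1. With an offset, shares of 54% and 82% left a gap of at most 0.09 log2, so a mixture may hold. The mixture cannot be told apart from a partial effect of KDM4E in each embryo, nor from a difference in stage or collection time. It stays open for the 55 genes that passed both single tests as higher in KDM4E-SCNT, where a joint test replaced a weaker bound and limma called 0 genes (lowest adjusted p = 0.0596, 328 genes with an unadjusted joint p under 0.05), and for the 97 histone genes, of which 27 had such a joint p but which, each set against its higher group, did not pass limma's fry as a pair of sets (Bonferroni adjusted p = 0.286, and 1 under median-ratio scaling).

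TIMP1, LUM and POSTN were high in KDM4E-SCNT replicate 2, at 135.01, 84.6 and 28.61 FPKM, against 5.02, 13.38 and 0.65 FPKM in replicate 1. LGALS1, SPARC and DCN were also higher there (127.17, 53.32 and 13.12 against 10.94, 10.4 and 2.9 FPKM), and fibroblast markers summed to 578 against 138 FPKM. Fibroblast-type cells rich in collagen are argued against, since COL1A1, COL1A2 and COL3A1 together came to 4.35 FPKM, 1.75% of the 248.22 FPKM of TIMP1, LUM and POSTN. Other cells with these markers and little collagen stay open, and no other biological explanation was tested for this difference within a group.

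For IVF against SCNT, 8680 genes were called and the highest of the other splits of the 6 libraries called 1, but 10 splits, of which 1 reached the real count, are too few for a share under 0.05.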
